A study of Mus musculus with 48 samples.

How the data were processed

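RNA was extracted by the authors from whole kidney with RNeasy kits and DNase, and libraries were made with the Kapa mRNA Hyperprep kit. The strand and the read depth are not given in the sources used here. The submitters' notes name STAR for alignment to GRCm38, RSEM for quantification and DESeq for their own comparisons, without versions. The deposited values were read as log2(TPM + 1) made by the authors, because raising 2 to each value and subtracting 1 gave numbers that sat on 0.01 steps in 100% of cases and summed to 999764.29 to 999861.77 TPM per library. The table held 54134 gene symbols, of which 21139 were at 0 in every library. For positions, 52982 symbols matched 1 gene of GENCODE M21, 111 matched several (Ddit3 among them, so no position is given for it) and 1041 matched none.

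Columns were matched to the labels by their header lines, which fitted in 42 of 42 libraries, and 6 labelled samples had no column. The table header gives 100 ug poly I:C, and the label states the dose for 3 samples. The text of the design names 6 mice in each of 8 groups, while the labels give 7 unheated and 5 heated poly I:C mice at Tcmax, and labels were kept as given. Each library came from its own animal. Titles carry the prefixes 14, 15 or 16, whose meaning is not given in the sources used here, and they were used as a covariate in an alternative.

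The comparisons, the filter, the tests, the gene lists and the first 9 alternatives were set before the data were examined, for 48 samples and before the unit was known. Genes with at least 10 TPM in at least 5 libraries were tested (9647 genes). Comparisons were fitted on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per group over all libraries and empirical Bayes moderation with a trend, 2-sided. Adjusted p is Benjamini-Hochberg within a comparison, and a gene passed at 0.05. The 13 comparisons were heat in each injection and time point, poly I:C in each heat state and time point, the interaction of heat and poly I:C at each time point, the difference of the heat effect between time points in each injection, and 1 day against Tcmax in unheated saline mice. Principal components used the same genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

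Gene lists (33 lists, 502 genes, written from general knowledge) were tested with camera of limma at a preset correlation of 0.01, with p adjusted over the lists of a comparison. A second camera test estimated the correlation within each list, and the rotation test fry was run beside them. Lists with fewer than 3 measured genes were not tested, which left 29. The lists cover heat shock chaperones, unfolded protein response, immediate early genes, interferon-stimulated genes, NF-kB and inflammatory genes, acute-phase genes, complement, coagulation and fibrinolysis, tubular injury markers, segments of the tubule, podocytes, endothelium, macrophages and monocytes, red blood cells, platelets, adipocytes, extracellular matrix, cell cycle, metabolism and stress pathways. The camera direction compares a list with all other genes, so it can differ from the sign of the list's own median.

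Genes were named by a rule. For the heat comparisons and for poly I:C in unheated mice these were up to 8 genes with the highest and 8 with the lowest change that passed and had a mean of at least 50 TPM, and for the others up to 5 and 5, without predicted genes and clones. Added to these were up to 4 members of each list with the smallest p, and a fixed panel of chaperone, coagulation, injury, interferon, cytokine, glucocorticoid and transporter genes. Star, Cyp11b1 and Cyp11a1 came from a list of adrenal markers. Hyou1, Cyp24a1 and the other genes outside the rule were chosen after their values were seen. Some genes that met the rule are not reported here.

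The test was tried on simulated data, drawn once per comparison as normal values with the mean and residual SD of each of the 9647 genes, with 100 genes shifted by log2 1 and 100 by log2 2 in 1 group. Of genes shifted by log2 2, 89 to 98 passed, and of genes shifted by log2 1, 54 to 90 passed. Between 5 and 13 unshifted genes passed, and 0 genes passed in the wrong direction. A list of 20 shifted genes passed in each of the 13 comparisons, and 0 of 20 unshifted lists passed. The run was set to stop if a shifted list failed or a gene passed in the wrong direction, so those outcomes carry no weight. Genes were drawn independently of each other, with the same SD in every group. The trial therefore does not bear on lists of correlated genes or on groups of unequal spread.

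The first alternatives were no filter on low values, a mean of at least 50 TPM (2578 genes), quantile normalization, equal medians, an offset of 10 in place of 1, only the groups compared, sample weights, the title number as covariate and leaving out 1 library at a time. Added later were a filter at 1 TPM in 4 libraries (18047 genes), leaving out the library labelled unheated poly I:C Tcmax replicate 6 everywhere, TPM rescaled over nuclear protein-coding genes, and the number of detected genes as covariate. Unsequenced organs, core temperatures and outcome data of the mice were not analysed here.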

Results

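The measurements were messenger RNA levels in whole kidney from male C57BL/6J mice, 1 library per animal, in a design crossing heat stress, an injection and a time point. The injection was saline or poly I:C, a synthetic double-stranded RNA that stands in for a viral infection, at 100 ug in the header of the table. Mice were sampled at Tcmax, taken here as the time of maximum core temperature because the labels do not define it, or 1 day later. The labels cover 48 samples in 8 groups, and 42 of them have a column in the table. At Tcmax the table holds 4 unheated saline, 6 heated saline, 6 unheated poly I:C and 5 heated poly I:C libraries. At 1 day it holds 6 unheated saline, 6 heated saline, 4 unheated poly I:C and 5 heated poly I:C libraries. Values were log2(TPM + 1), where TPM is the share of transcripts scaled to a fixed total, so the number of reads behind each library is unknown and no counting error can be given. Each library had 13816 to 15066 genes at 1 TPM or more, and its 10 highest genes held 21.5% to 30.7% of all TPM. In what follows, ± after a log2 fold change is its standard error and ± after a TPM mean is the SD over the n libraries of that group, and p is the adjusted p of limma.

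In the principal components of all 9647 tested genes, the heated Tcmax libraries lay at 26.7 to 40.4 on the first component, which held 20.8% of the variance. The library labelled unheated poly I:C Tcmax replicate 6 lay at 38.9 on that component, among the heated libraries. Its Hspa1a, an inducible heat shock chaperone, stood at 2133.5 TPM, while the next highest of its group had 10.4 TPM. Heated poly I:C Tcmax libraries had 2156.9 ± 400.56 TPM (n = 5). Its Irf7, a regulator of the interferon response, stood at 285.3 TPM, against 333 ± 94.6 TPM in heated poly I:C (n = 5) and 6.90 ± 1.67 TPM in heated saline libraries (n = 6). The library kept its label in every comparison, and counts without it are given beside those it enters. The library labelled heated saline 1 day replicate 4 carried adrenal markers, with Star at 307 TPM, Cyp11b1 at 204 TPM and Cyp11a1 at 149 TPM. Counts without that library are given where they differ by more than 1.5 times.

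**Figure D1:**
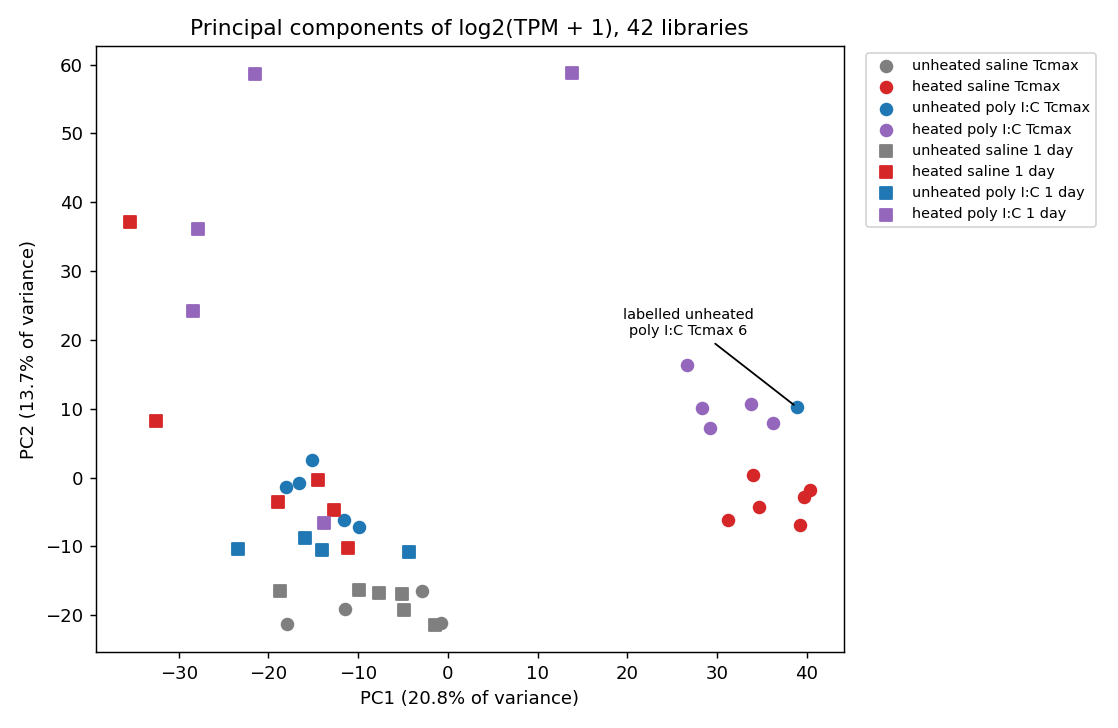
Each point is 1 of 42 libraries placed by its first (horizontal, 20.8% of variance) and second (vertical, 13.7%) principal component, in component units, with circles for Tcmax and squares for 1 day. The heated Tcmax libraries sit at 26.7 to 40.4 on the first component, with the library labelled unheated poly I:C Tcmax replicate 6 at 38.9 among them.

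Heated against unheated saline mice at Tcmax (n = 6 and 4) addressed the kidney response at peak temperature without poly I:C. The inducible chaperones Hspa1b (chromosome 17, 34956436 to 34959238, GRCm38) and Hspa1a (chromosome 17, 34969190 to 34972156) rose by log2 7.10 ± 0.90 (adjusted p = 6.1e-07) and 6.94 ± 0.98 (adjusted p = 3.2e-06). The small chaperone Hspb1 (chromosome 5, 135887919 to 135889563) rose by 5.45 ± 0.76 (adjusted p = 3.2e-06), from 10.7 ± 5.01 TPM to 483 ± 71.5 TPM. The immediate early transcription factor Jun (chromosome 4, 95049034 to 95052222) rose by 3.69 ± 0.53 (adjusted p = 4.7e-06), and the stress-induced transcription factor Ddit3 rose by 3.01 ± 0.26 (adjusted p = 6.6e-10). The splicing factor Srsf5 changed by -1.62 ± 0.20 (adjusted p = 3.6e-07). The nuclear non-coding RNA Neat1 changed by -1.89 ± 0.26 (adjusted p = 2.6e-06) and the monocarboxylate carrier Slc16a9 by -1.87 ± 0.33 (adjusted p = 7.5e-05). Each of these genes was past every unheated library in 6 of 6 heated libraries. Of 22 heat shock chaperones, 22 rose and 0 fell (median 1.89, camera adjusted p = 3.3e-35, adjusted p = 0.038 with an estimated correlation). Of 18 unfolded protein response genes, 11 rose, 3 fell and 4 did not pass, and 13 rose when adjusted over the list alone. Among them Atf4, a translation-stress regulator, rose by 2.31 ± 0.30 (adjusted p = 8.5e-07), and the degradation factor Edem1 changed by -0.74 ± 0.14. The list call (camera adjusted p = 6.1e-10) was lost with an estimated correlation (adjusted p = 0.065). Of 13 immediate early genes, 10 rose and 0 fell (12 over the list alone), with Nr4a1 at 3.83 ± 0.56 and Fos at 3.55 ± 0.66 (camera adjusted p = 7.4e-13, adjusted p = 0.16 with an estimated correlation). Of 12 glucocorticoid targets, 5 rose and 1 fell, with Tsc22d3 at 1.84 ± 0.24 and Klf9 at -0.81 ± 0.21 (camera adjusted p = 0.002, adjusted p = 0.81 with an estimated correlation). Of 5 osmotic response genes, 2 rose and 1 fell, among them the inositol carrier Slc5a3 at 1.85 ± 0.24 (camera adjusted p = 0.016, adjusted p = 0.24 with an estimated correlation).

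In limma, 2581 of 9647 genes passed in that comparison, 523 higher and 2058 lower, of which 152 and 220 changed at least 2-fold. The median of all tested genes stood at -0.18, and with equal medians 1145 genes were higher and 1170 lower. Quantile normalization gave 916 higher and 1202 lower genes. Of the 2578 genes with a mean of at least 50 TPM, 745 passed. The osmotic list no longer passed with quantile normalization (adjusted p = 0.068), and the glucocorticoid list no longer passed with equal medians (adjusted p = 0.055).

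Heated against unheated mice given poly I:C, sampled at Tcmax (n = 5 and 6), put the same question after a mimic of viral infection. Hspa1a rose by 6.48 ± 0.92 (adjusted p = 6.9e-06), Hspa1b by 6.01 ± 0.84, Hspb1 by 4.78 ± 0.72 (adjusted p = 1.3e-05) and Jun by 3.27 ± 0.50. Dnajb1, a partner of the Hspa1 chaperones, rose by 3.41 ± 0.46 and the co-chaperone Bag3 by 2.64 ± 0.36 (adjusted p = 6.0e-06). Srsf5 changed by -1.29 ± 0.18 (adjusted p = 8.0e-06), Slc16a9 by -1.72 ± 0.31, and Mat2a, which makes the methyl donor S-adenosylmethionine, by -1.33 ± 0.20. Hspa1a was above the unheated mean in 5 of 5 heated libraries but above every unheated library in 2 of 5, because of the library labelled unheated replicate 6. Without that library the changes were 7.77 for Hspa1a, 7.22 for Hspa1b, 5.76 for Hspb1, 4.10 for Dnajb1 and 3.96 for Jun. Whether these differ from the saline changes was tested by the interaction, where none of them passed. Of 22 heat shock chaperones, 21 rose and 0 fell (22 over the list alone, median 1.63, camera adjusted p = 1.9e-43, adjusted p = 0.012 with an estimated correlation). Of 13 immediate early genes, 9 rose and 0 fell (12 over the list alone), with Nr4a1 at 3.13 ± 0.52 (camera adjusted p = 9.8e-15, adjusted p = 0.15 with an estimated correlation). Of 18 unfolded protein response genes, 6 rose and 3 fell (8 and 3 over the list alone), with Ddit3 at 1.04 ± 0.25 (adjusted p = 0.0025) and Edem1 at -0.79 ± 0.13 (camera adjusted p = 0.00026, adjusted p = 0.43 with an estimated correlation). Glucocorticoid targets (4 rose, 1 fell, Tsc22d3 at 1.38 ± 0.22) passed camera at adjusted p = 0.00032, lost with an estimated correlation (adjusted p = 0.72), and so did the osmotic list (2 rose, 1 fell, Slc5a3 at 1.55 ± 0.23), with adjusted p = 0.0087 and 0.23.

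That comparison gave 1982 genes, 312 higher and 1670 lower, with 98 and 114 at least 2-fold. Genes higher with heat in both injections numbered 249 against 16.9 expected if the calls were independent. Genes lower in both numbered 1305 against 356. The groups of these comparisons share no library, but the spread of each gene was estimated over all libraries for both. The calls were therefore not independent, here and in the overlaps given below, and the expected numbers are only a reference. The median of all genes was -0.16, and with equal medians 713 were higher and 839 lower. Sample weights gave 4118 genes, and of genes with a mean of at least 50 TPM 536 passed. Without the library labelled unheated poly I:C Tcmax replicate 6, 2900 genes passed, 450 higher and 2450 lower.

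The interaction at Tcmax asked whether the heat effect differed between poly I:C and saline mice. An unadjusted limma p below 0.05 was reached by 283 genes, fewer than the share of 0.05 of 9647 genes expected by chance. Only Ddit3 passed, with a difference of -1.96 ± 0.36 (adjusted p = 0.032). Its level was 9.20 ± 1.88 TPM in unheated saline (n = 4), 81.5 ± 17.0 TPM in heated saline (n = 6), 61.6 ± 38.0 TPM in unheated poly I:C (n = 6) and 115 ± 12.9 TPM in heated poly I:C libraries (n = 5). The unfolded protein response list passed camera as lower (median -0.38, 0 rose, 1 fell, adjusted p = 4.8e-09), lost with an estimated correlation (adjusted p = 0.15). Ddit3 no longer passed without the low-value filter (adjusted p = 0.12), with an offset of 10 (adjusted p = 0.44), with only the groups compared (adjusted p = 0.13) or with the title number as covariate (adjusted p = 0.068). It also no longer passed without any 1 of 10 libraries, namely heated poly I:C Tcmax replicates 1, 2, 3 and 4, heated saline replicates 3, 4 and 5, unheated saline replicates 3 and 6 and unheated poly I:C replicate 4, with 0 genes passing in each case, and its p ranged from 0.00059 to 0.44 over all alternatives. Without unheated saline replicate 2, 2 genes passed, and without the library labelled unheated poly I:C replicate 6, 1 gene passed.

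Poly I:C against saline in unheated mice at Tcmax (n = 6 and 4) addressed the response to poly I:C alone. Irf7 (chromosome 7, 141262706 to 141266481) rose by 4.85 ± 0.21 (adjusted p = 2.2e-20), from 11.7 ± 1.40 TPM to 377 ± 133 TPM. The interferon-induced GTPase Gbp6 rose by 3.90 ± 0.26 (adjusted p = 1.4e-14), the viral tether Bst2 by 3.35 ± 0.20 (adjusted p = 5.2e-16). B2m (chromosome 2, 122147686 to 122153083), the light chain of class I antigen presentation, rose by 2.95 ± 0.12 (adjusted p = 1.4e-20). The chemokine Cxcl10 rose by 1.82 ± 0.31 (adjusted p = 8.7e-05). Hba-a1 (chromosome 11, 32283511 to 32284465), an alpha chain of hemoglobin, changed by -4.02 ± 0.45 (adjusted p = 3.5e-08), and Hbb-bs (chromosome 7, 103826534 to 103828096), a beta chain, by -3.13 ± 0.42 (adjusted p = 1.0e-06). Irf7, B2m and Hba-a1 were past every saline library in 6 of 6 poly I:C libraries. Of 27 interferon-stimulated genes, 27 rose and 0 fell (median 1.81, camera adjusted p = 3.3e-60, adjusted p = 4.2e-06 with an estimated correlation). Of 14 complement genes, 10 rose and 0 fell, with C4b at 2.65 ± 0.26 and the protease C1ra at 1.62 ± 0.16 (camera adjusted p = 1.5e-13, adjusted p = 0.0014 with an estimated correlation). Of 6 red blood cell genes, 0 rose and 4 fell (median -3.21, camera adjusted p = 1.0e-14, adjusted p = 4.2e-06 with an estimated correlation). Of 13 mitochondrially encoded genes, 0 rose and 6 fell (7 over the list alone), with mt-Nd4 at -0.44 ± 0.08 and mt-Nd5 at -0.55 ± 0.10 (camera adjusted p = 2.8e-14, adjusted p = 0.0014 with an estimated correlation). Of 6 macrophage and monocyte genes 3 rose and 0 fell (4 over the list alone), among them C1qa at 1.28 ± 0.24, lost with an estimated correlation (adjusted p = 0.0057 and 0.35).

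Limma gave 478 genes for poly I:C in unheated Tcmax mice, 447 higher and 31 lower. Quantile normalization gave 219 higher and 112 lower genes and ended the calls of mt-Nd4 (adjusted p = 0.17) and mt-Nd5 (adjusted p = 0.52), equal medians gave 286 genes (194 higher, 92 lower), and sample weights gave 1321. With TPM rescaled over nuclear protein-coding genes 286 passed, with the number of detected genes as covariate 310, and with a mean of at least 50 TPM 268. Without the library labelled unheated poly I:C replicate 6, 462 passed and the heat shock chaperone list, called at adjusted p = 0.0057 with it, had adjusted p = 0.68 without it and the opposite direction. That list did not pass with an estimated correlation either (adjusted p = 0.75), nor with sample weights (adjusted p = 0.96), fry (adjusted p = 0.15) or a mean of at least 50 TPM (adjusted p = 0.14).

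Poly I:C against saline in heated mice at Tcmax (n = 5 and 6) gave the poly I:C effect during heat. Irf7 rose by 5.38 ± 0.20 (adjusted p = 1.0e-22), Gbp6 by 3.55 ± 0.24, Cxcl10 by 2.56 ± 0.29 (adjusted p = 2.1e-08) and Irgm1, a GTPase of antimicrobial autophagy, by 2.96 ± 0.24 (adjusted p = 9.1e-12). Hba-a2 changed by -4.03 ± 0.50 (adjusted p = 2.2e-07) and Hbb-bs by -3.76 ± 0.39 (adjusted p = 3.1e-09). Each was past every saline library in 5 of 5 poly I:C libraries. Of 27 interferon-stimulated genes, 27 rose and 0 fell (median 2.02, camera adjusted p = 5.3e-91, adjusted p = 5.3e-08 with an estimated correlation). Of 14 complement genes 10 rose and 0 fell, with C4b at 3.06 ± 0.24 and C3 at 2.52 ± 0.31 (camera adjusted p = 4.9e-19, adjusted p = 0.00014 with an estimated correlation). Red blood cell genes gave 0 risen and 4 fallen of 6 (median -3.63, camera adjusted p = 2.2e-22, adjusted p = 5.3e-08 with an estimated correlation). Mitochondrially encoded genes gave 0 risen and 4 fallen of 13 (7 over the list alone, median -0.27, mt-Cytb at -0.35 ± 0.07, camera adjusted p = 5.3e-14, adjusted p = 0.0017 with an estimated correlation). The 321 genes comprised 305 higher and 16 lower. Of the higher genes 193 were also higher in unheated mice, against 14.1 expected. Quantile normalization gave 205 genes (157 higher, 48 lower), ended the call of mt-Cytb (adjusted p = 0.74) and left the mitochondrial list at adjusted p = 0.064. With only the groups compared 616 genes passed, with sample weights 802, with a mean of at least 50 TPM 129, and without heated poly I:C Tcmax replicate 3, 207.

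**Figure D2:**
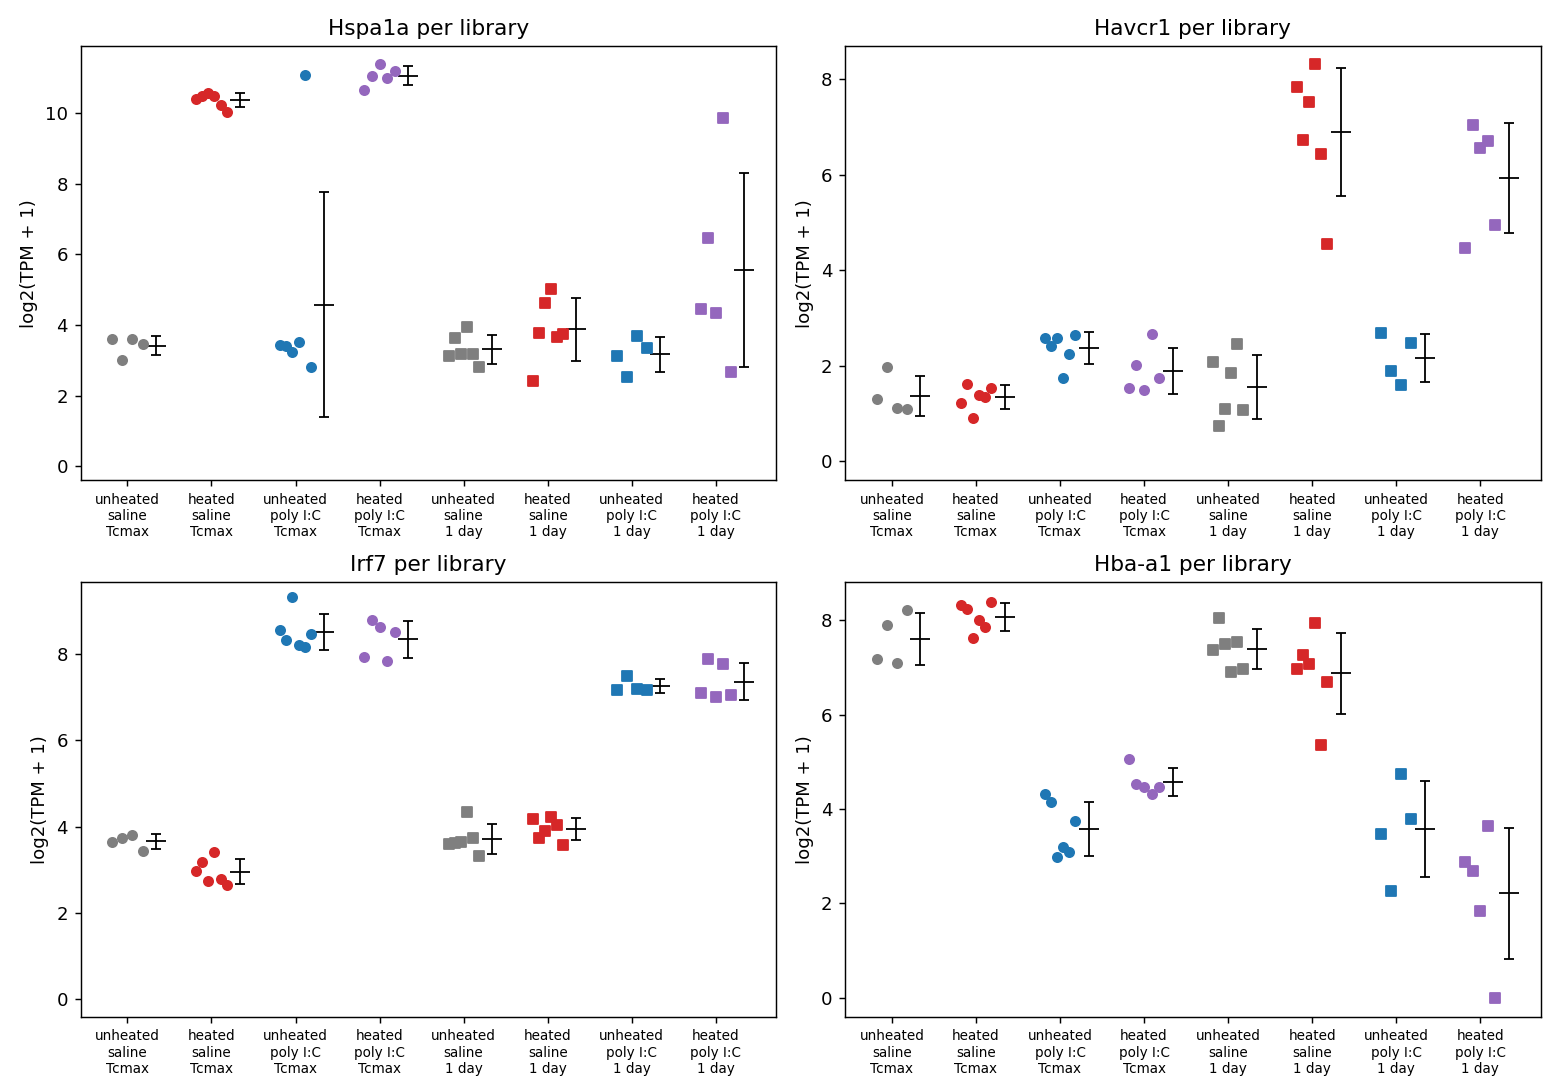
Each point is 1 library, the vertical axis is log2(TPM + 1), and the bar beside each group is the mean with its SD, for Hspa1a, Havcr1, Irf7 and Hba-a1 in the 8 groups. Hspa1a was high in the heated Tcmax libraries (1321.9 ± 175.47 TPM in saline) and in the library labelled unheated poly I:C Tcmax replicate 6 (2133.5 TPM), Havcr1 in heated 1 day libraries, Irf7 in all poly I:C groups and Hba-a1 in all saline groups.

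Heated against unheated saline mice at 1 day (n = 6 and 6) addressed what remained or appeared after recovery from heat. Havcr1 (chromosome 11, 46735080 to 46779578), the tubular injury marker KIM-1, rose by 5.34 ± 0.42 (adjusted p = 2.8e-11), from 2.22 ± 1.5 TPM to 157 ± 107 TPM. Lcn2 (chromosome 2, 32384633 to 32388252), the injury marker NGAL, rose by 3.97 ± 0.75 (adjusted p = 0.00066). Cyp4a14 (chromosome 4, 115486200 to 115496142), a fatty acid hydroxylase, rose by 4.0 ± 0.53 (adjusted p = 5.2e-06), and Fgg (chromosome 3, 83007724 to 83015049), the gamma chain of fibrinogen, by 2.86 ± 0.62 (adjusted p = 0.0022). Egf (chromosome 3, 129677565 to 129755316), a growth factor of the distal tubule, changed by -1.5 ± 0.28 (adjusted p = 0.00051), and the organic anion carrier Slc22a7 by -1.5 ± 0.18 (adjusted p = 1.7e-06). Havcr1, Lcn2, Cyp4a14 and Egf were past every unheated library in 6 of 6 heated libraries, and Fgg in 5 of 6. Without heated saline 1 day replicate 4 the changes were 3.32 for Lcn2 and 2.26 for Fgg. Hspa1a did not pass (0.56 ± 0.87, adjusted p = 0.69). Of 11 tubular injury markers, 8 rose and 0 fell (11 over the list alone, median 1.42, camera adjusted p = 1.1e-08, adjusted p = 0.13 with an estimated correlation). Of 22 proximal tubule genes, 0 rose and 9 fell (1 and 10 over the list alone), with the androgen-regulated Kap at -0.62 ± 0.11 and the carrier Slc22a8 at -0.62 ± 0.14 (camera adjusted p = 3.0e-13, adjusted p = 0.056 with an estimated correlation). Of 18 unfolded protein response genes, 13 rose and 0 fell (15 over the list alone), with the endoplasmic reticulum proteins Sdf2l1 at 1.66 ± 0.22 (adjusted p = 5.2e-06), Manf at 1.38 ± 0.21 and Hspa5 at 1.16 ± 0.19 (camera adjusted p = 2.3e-09, adjusted p = 0.056 with an estimated correlation). Of 20 fatty acid oxidation genes, 9 rose and 1 fell (10 and 1 over the list alone), with the fatty acid hydroxylase Cyp4a10 at 1.64 ± 0.26 (camera adjusted p = 7.6e-05, adjusted p = 0.28 with an estimated correlation). Of 9 acute-phase genes, 7 rose and 0 fell, with C3 at 1.51 ± 0.30 (camera adjusted p = 0.00064, adjusted p = 0.25 with an estimated correlation). Of 27 interferon-stimulated genes, 10 rose and 0 fell (14 over the list alone), with Oas1a at 1.07 ± 0.23 (camera adjusted p = 0.0023, adjusted p = 0.39 with an estimated correlation). Of 11 NRF2 targets, 6 rose and 0 fell (7 over the list alone), with Gsta1 at 3.0 ± 0.54 (camera adjusted p = 0.0011, adjusted p = 0.25 with an estimated correlation). Of 6 red blood cell genes, 0 rose and 1 fell, Hbb-bt at -1.10 ± 0.32, and the list passed camera (adjusted p = 0.00068, adjusted p = 0.056 with an estimated correlation). Hbb-bt no longer passed without heated saline 1 day replicate 3 (adjusted p = 0.068) or without the low-value filter (adjusted p = 0.057).

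The 1 day heat effect in saline mice comprised 1317 genes, 1084 higher and 233 lower, with a median of all genes at 0.17. The split of higher and lower turned with equal medians (236 higher, 593 lower) and quantile normalization (367 higher, 492 lower), so it is reported only relative to that shift. Without the low-value filter 784 genes passed, with a mean of at least 50 TPM 749, and with sample weights 2012. Counts were 551 without the library labelled heated saline 1 day replicate 4, 832 without heated replicate 3, 867 without unheated replicate 1 and 839 without unheated replicate 3. The lists of NRF2 targets (adjusted p = 0.083) and interferon-stimulated genes (adjusted p = 0.13) no longer passed with a mean of at least 50 TPM.

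Heated against unheated mice given poly I:C, sampled at 1 day (n = 5 and 4), asked the same after poly I:C. Lcn2 rose by 5.39 ± 0.87 (adjusted p = 8.7e-05), from 5.03 ± 1.29 TPM to 568 ± 469 TPM. Havcr1 rose by 3.78 ± 0.49 (adjusted p = 1.1e-05) and Krt20, a keratin of injured tubules, by 4.30 ± 0.84 (adjusted p = 0.00051). The metal-binding Mt2 rose by 3.39 ± 0.57 (adjusted p = 0.00011), the lipid droplet protein Plin2 by 3.10 ± 0.55 (adjusted p = 0.00019). Hspb1 rose by 3.93 ± 0.79 (adjusted p = 0.00065) and Fgg by 3.45 ± 0.72 (adjusted p = 0.00089). Fga (chromosome 3, 83026076 to 83033627), the fibrinogen alpha chain, rose by 3.22 ± 0.71 (adjusted p = 0.0015). Gatm (chromosome 2, 122594467 to 122611303), the first enzyme of creatine synthesis, changed by -3.31 ± 0.59 (adjusted p = 0.0002). Egf changed by -1.52 ± 0.32 (adjusted p = 0.0011) and the isoprenoid enzyme Idi1 by -1.71 ± 0.27 (adjusted p = 8.1e-05). Hspa1a did not pass (2.39 ± 1.01, adjusted p = 0.085). It passed without heated poly I:C 1 day replicate 6 (3.11, adjusted p = 0.017), without the library labelled unheated poly I:C Tcmax replicate 6 (adjusted p = 0.0093) and with sample weights (1.84, adjusted p = 0.016), and stood at 1.32 without replicate 5 (adjusted p = 0.34). Havcr1 was above every unheated library in 5 of 5 heated libraries, Lcn2, Krt20, Fgg and Fga in 4 of 5. Without heated poly I:C 1 day replicate 6 the changes were larger, at 6.72 for Lcn2, 5.35 for Krt20, 4.68 for Hspb1, 4.32 for Fgg, 4.07 for Fga, 4.04 for Mt2, 3.77 for Plin2 and -4.12 for Gatm. Krt20 stood at 3.48 without replicate 5 and Fga at 2.63 without replicate 3. Of 11 tubular injury markers, 9 rose and 0 fell (median 1.96, camera adjusted p = 1.3e-07, adjusted p = 0.17 with an estimated correlation). Of 22 proximal tubule genes, 1 rose and 16 fell (2 and 18 over the list alone), with Slc22a8 at -1.05 ± 0.16 (camera adjusted p = 1.6e-09, adjusted p = 0.17 with an estimated correlation). Of 11 genes of the loop of Henle and distal tubule, 0 rose and 7 fell (9 over the list alone). Among them were the claudin Cldn10 at -0.93 ± 0.15 and the salt carrier Slc12a3 at -0.75 ± 0.16 (camera adjusted p = 2.7e-06, adjusted p = 0.17 with an estimated correlation). Of 12 glucocorticoid targets, 10 rose and 0 fell (12 over the list alone, median 2.07), with Per1 at 1.84 ± 0.37 and Fkbp5 at 1.60 ± 0.32 (camera adjusted p = 1.6e-09, adjusted p = 0.17 with an estimated correlation). Of 20 fatty acid oxidation genes, 12 rose and 1 fell (13 and 1 over the list alone), with the lipase inhibitor Angptl4 at 2.41 ± 0.46 (camera adjusted p = 6.7e-07, adjusted p = 0.17 with an estimated correlation). Of 17 cholesterol synthesis genes 0 rose and 6 fell, with Idi1 among them (camera adjusted p = 4.6e-05, adjusted p = 0.24 with an estimated correlation). Of 11 NRF2 targets 8 rose and 0 fell, with Gsta1 at 3.51 ± 0.63 (camera adjusted p = 4.3e-05, adjusted p = 0.17 with an estimated correlation). Of 18 oxidative phosphorylation genes 0 rose and 7 fell, with Sdha at -0.43 ± 0.08 (camera adjusted p = 3.4e-05, adjusted p = 0.24 with an estimated correlation).

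Further lists also passed in that comparison and were lost with an estimated correlation. Of 6 macrophage and monocyte genes, 0 rose and 5 fell, with the receptor Csf1r at -0.80 ± 0.14 (adjusted p = 0.0018 and 0.17). Of 22 heat shock chaperones 8 rose and 0 fell, with Hspd1 at 1.17 ± 0.22 (adjusted p = 6.6e-05 and 0.40). Of 13 immediate early genes 8 rose and 0 fell, with Myc at 1.92 ± 0.46 (adjusted p = 4.3e-05 and 0.29). Of 5 NF-kB and inflammatory genes 4 rose and 0 fell, with Nfkb2 at 0.85 ± 0.22 (adjusted p = 0.0064 and 0.21). Of 9 acute-phase genes 5 rose and 1 fell, with Lrg1 at 2.95 ± 0.64 (adjusted p = 0.001 and 0.21). Of 8 p53 targets 3 rose and 0 fell, with the cell cycle inhibitor Cdkn1a at 2.85 ± 0.61 (adjusted p = 0.016 and 0.21). Of 13 circadian clock genes 4 rose and 0 fell, with Ciart at 2.00 ± 0.39 (adjusted p = 0.019 and 0.17). The acute-phase list (adjusted p = 0.057) and the circadian list (adjusted p = 0.34) no longer passed with a mean of at least 50 TPM. Without heated poly I:C 1 day replicate 6, Lrg1 stood at 3.90 and Cdkn1a at 3.61, and without replicate 5 Cdkn1a stood at 2.24.

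In all, 2106 genes passed for heat after poly I:C at 1 day, 1075 higher and 1031 lower, and 390 of the higher genes were also higher in saline mice, against 121 expected. The count rested on a spread shared with the other 6 groups. With only the 2 groups compared, 8 genes passed (7 higher, 1 lower). Among the genes named above these included only Havcr1 (adjusted p = 0.028) and Gsta1 (adjusted p = 0.024), and Lcn2 had adjusted p = 0.089 and Krt20 adjusted p = 0.11. Equal medians gave 880 higher and 1545 lower genes. With a mean of at least 50 TPM 1085 passed, and without heated poly I:C 1 day replicate 3, 1138 passed.

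Poly I:C against saline in unheated mice at 1 day (n = 4 and 6) showed what persisted of the poly I:C response. Irf7 rose by 3.54 ± 0.21 (adjusted p = 1.3e-15), from 12.4 ± 3.56 TPM to 152 ± 17.5 TPM, Gbp6 by 3.05 ± 0.26 and B2m by 2.29 ± 0.12 (adjusted p = 1.1e-16). Hba-a1 changed by -3.82 ± 0.45 (adjusted p = 3.2e-07) and Hba-a2 by -3.76 ± 0.54. Each was past every saline library in 4 of 4 poly I:C libraries. Of 27 interferon-stimulated genes, 17 rose and 0 fell (26 over the list alone, median 1.15, camera adjusted p = 6.6e-57, adjusted p = 7.1e-06 with an estimated correlation). Of 14 complement genes, 9 rose and 0 fell (10 over the list alone), with C4b at 2.16 ± 0.26 (camera adjusted p = 1.5e-18, adjusted p = 0.00017 with an estimated correlation). Of 6 macrophage and monocyte genes 3 rose and 0 fell (4 over the list alone), with C1qa at 1.28 ± 0.24 (camera adjusted p = 6.4e-08, adjusted p = 0.011 with an estimated correlation). Of 6 red blood cell genes, 0 rose and 4 fell (median -3.54, camera adjusted p = 2.0e-29, adjusted p = 3.4e-09 with an estimated correlation). Of 13 mitochondrially encoded genes 0 rose and 0 fell, while the list passed as lower (median -0.14, camera adjusted p = 2.7e-09, adjusted p = 0.013 with an estimated correlation). That list did not pass with quantile normalization (adjusted p = 0.59) or with the rotation test fry (adjusted p = 0.15). The 97 genes comprised 92 higher and 5 lower, and 84 of the higher ones were also higher at Tcmax, against 4.26 expected. Sample weights gave 441 genes, a mean of at least 50 TPM 36, and leaving out unheated poly I:C 1 day replicate 2 gave 53.

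Poly I:C against saline in heated mice at 1 day (n = 5 and 6) gave the poly I:C effect after heat. Gbp6 rose by 3.95 ± 0.24 (adjusted p = 2.1e-15), Irf7 by 3.42 ± 0.20 (adjusted p = 5.1e-16), Cxcl10 by 2.14 ± 0.29 (adjusted p = 3.3e-06) and Ddit3 by 1.81 ± 0.25 (adjusted p = 3.8e-06). Hba-a1 changed by -4.67 ± 0.43 (adjusted p = 3.2e-10). Gbp6, Irf7 and Hba-a1 were past every saline library in 5 of 5 poly I:C libraries. The endoplasmic reticulum genes Sdf2l1, at -1.60 ± 0.23 (adjusted p = 1.0e-05), and Pdia6, a disulfide isomerase, at -0.80 ± 0.13 (adjusted p = 7.0e-05), fell. Of 27 interferon-stimulated genes, 15 rose and 0 fell (19 over the list alone, median 0.72, camera adjusted p = 2.0e-16, adjusted p = 0.033 with an estimated correlation). Of 6 red blood cell genes, 0 rose and 4 fell (median -2.95, camera adjusted p = 1.6e-07, adjusted p = 0.0024 with an estimated correlation). Of 18 unfolded protein response genes, 1 rose and 11 fell (median -0.66, camera adjusted p = 0.00011, adjusted p = 0.37 with an estimated correlation). Of 12 glucocorticoid targets, 10 rose and 0 fell (12 over the list alone, median 1.42), with Fkbp5 at 1.28 ± 0.29 (camera adjusted p = 4.1e-10, adjusted p = 0.14 with an estimated correlation). Of 14 complement genes 4 rose and 0 fell, with C4b at 1.98 ± 0.24 (camera adjusted p = 0.0023, adjusted p = 0.40 with an estimated correlation). The 1280 genes comprised 571 higher and 709 lower. With only the 2 groups compared 41 genes passed (34 higher, 7 lower), with Gbp6, Irf7, Hba-a1, Ddit3, Sdf2l1 and C4b among them, while Cxcl10 (adjusted p = 0.06), Pdia6 (adjusted p = 0.12) and Fkbp5 (adjusted p = 0.22) did not pass. Sample weights gave 2080 genes. Without heated poly I:C 1 day replicates 3, 5 or 6 in turn, 419, 579 and 2535 passed, and without heated saline replicate 4, 1990.

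The interaction at 1 day gave 7 genes, 0 higher and 7 lower, while 1627 genes had an unadjusted limma p below 0.05. Sdf2l1 differed by -1.82 ± 0.32 and Pdia6 by -1.01 ± 0.19 (both adjusted p = 0.012). Neither passed with only the groups compared (adjusted p = 0.16 and 0.25) or without unheated poly I:C 1 day replicate 3 (both adjusted p = 0.058), and Pdia6 did not pass with equal medians (adjusted p = 0.089). Sdf2l1 stood at 31.3 ± 11.5 TPM in heated saline libraries (n = 6) and at 9.00 ± 2.77 (n = 6), 10.4 ± 1.37 (n = 4) and 9.32 ± 2.49 TPM (n = 5) in the unheated saline, unheated poly I:C and heated poly I:C libraries. The other 5 genes, chosen because they passed, were the basement membrane collagen Col15a1 (-1.78 ± 0.32), the glycosylation subunit Ostc (-0.94 ± 0.18), the mitochondrial Stoml2 (-0.88 ± 0.18), the hydroxylase-like Ogfod3 (-0.84 ± 0.17) and the mitochondrial ribosome gene Mrpl3 (-0.84 ± 0.17). Col15a1 and Ostc did not pass without unheated poly I:C 1 day replicate 3 (both adjusted p = 0.058). Stoml2, Ogfod3 and Mrpl3 did not pass without that library (adjusted p = 0.12, 0.12 and 0.15) or without the low-value filter (0.064 each). With the title number as covariate 5 of the 7 genes passed, and Stoml2 and Ogfod3 did not (both adjusted p = 0.053). The chaperone Hyou1 (-1.13 ± 0.26, adjusted p = 0.057) and Fkbp5 (1.37 ± 0.42, adjusted p = 0.12) did not pass. Of 18 unfolded protein response genes 0 rose and 2 fell (11 over the list alone, camera adjusted p = 0.0003, adjusted p = 0.59 with an estimated correlation), and of 12 glucocorticoid targets 0 passed (11 rose over the list alone, median 1.37, camera adjusted p = 7.3e-13, adjusted p = 0.17 with an estimated correlation). Counts ranged from 0 with only the groups compared to 1038 with sample weights, with 33 at a mean of at least 50 TPM, 29 after quantile normalization and 11 with equal medians. Leaving out 1 of the 1 day libraries gave 4, 507, 4 and 831 genes for heated poly I:C replicates 3, 4, 5 and 6, and 4 and 88 for heated saline replicates 2 and 4. It gave 4, 13 and 18 for unheated saline replicates 1, 4 and 5, and 0 for unheated poly I:C replicate 3. Without the library labelled unheated poly I:C Tcmax replicate 6, 48 passed.

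The difference of the heat effect between 1 day and Tcmax was tested in each injection. In saline mice Havcr1 differed by 5.38 ± 0.63 (adjusted p = 1.3e-06), Lcn2 by 4.05 ± 1.13 (adjusted p = 0.0077), and Dbp, a clock output factor, by 2.84 ± 0.54 (adjusted p = 0.00038). Hspa1a differed by -6.38 ± 1.31 (adjusted p = 0.00078). Of 22 heat shock chaperones 0 rose and 18 fell (19 over the list alone, camera adjusted p = 3.8e-25, adjusted p = 0.082 with an estimated correlation). Of 8 podocyte genes 6 rose and 0 fell, with the surface protein Podxl at 1.31 ± 0.19 (camera adjusted p = 0.04, adjusted p = 0.62 with an estimated correlation). In poly I:C mice Havcr1 differed by 4.27 ± 0.66 (adjusted p = 9.8e-05), Lcn2 by 5.26 ± 1.18 (adjusted p = 0.0028), Mt2 by 3.69 ± 0.76 (adjusted p = 0.0017) and Fgg by 3.68 ± 0.97 (adjusted p = 0.0081). In these mice Dnajb1 differed by -2.79 ± 0.69 (adjusted p = 0.0053) and Hspa1a by -4.09 ± 1.37 (adjusted p = 0.033). The Hspa1a call ended with only the groups compared (adjusted p = 0.15), without the low-value filter (adjusted p = 0.097), and with detected genes as covariate (adjusted p = 0.058), and that of Dnajb1 with only the groups compared (adjusted p = 0.059). The Hspa1a call also ended without heated poly I:C 1 day replicates 1, 4 or 6, unheated poly I:C 1 day replicates 1, 3 or 4, or unheated poly I:C Tcmax replicates 1, 3, 4, 5 or 7, with adjusted p from 0.051 to 0.062. Its value was -5.38 without the library labelled unheated poly I:C Tcmax replicate 6, -5.16 without heated poly I:C 1 day replicate 5 and -3.37 without replicate 6, and that of Dnajb1 was -3.48 without the labelled Tcmax library. Without heated poly I:C 1 day replicate 6, Lcn2 differed by 6.59, Fgg by 4.55 and Mt2 by 4.34, and in saline mice Lcn2 differed by 3.41 without heated saline 1 day replicate 4. In saline mice 2820 genes passed, 2583 higher and 237 lower, with a median of 0.35. With equal medians 599 were higher and 828 lower. In poly I:C mice 1758 genes passed, 1410 higher and 348 lower, with 642 higher and 992 lower at equal medians, 970 with only the groups compared, 3659 with sample weights and 2449 without the library labelled unheated poly I:C Tcmax replicate 6. Of genes higher at Tcmax in saline, 113 were higher at 1 day, against 58.8 expected, and of those lower 48 were lower, against 49.7 expected.

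In unheated saline mice, 1 day against Tcmax (n = 6 and 4) gave 0 genes in limma, and the smallest adjusted p was 0.121. An unadjusted p below 0.05 was reached by 423 genes, fewer than the share of 0.05 of 9647 genes expected by chance. Sample weights gave 13 genes, no filter on low values 3, only the groups compared 2 and the filter at 1 TPM in 4 libraries 1. Without unheated saline Tcmax replicate 1 the count was 3, and without unheated saline 1 day replicate 3 it was 2. Of 13 circadian clock genes 0 passed over all genes, while 2 rose and 6 fell over the list alone (camera adjusted p = 3.0e-08, adjusted p = 0.00068 with an estimated correlation). The repressor Ciart stood at -1.67 ± 0.37 (adjusted p = 0.13), Nr1d2 at -0.67 ± 0.15 (adjusted p = 0.12) and the activator Arntl at 1.49 ± 0.40 (adjusted p = 0.41).

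**Figure D3:**
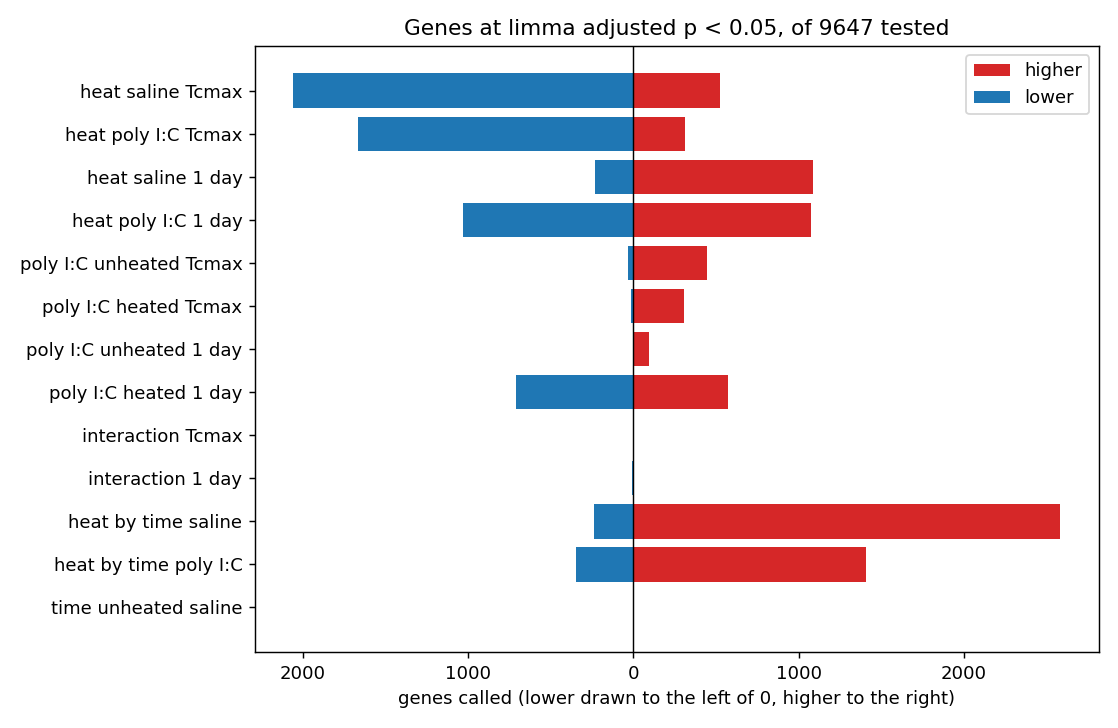
Bars give the number of genes, of 9647 tested, that passed in each of the 13 comparisons, with higher genes to the right of 0 and lower genes to the left. Heat at Tcmax in saline mice had 523 higher and 2058 lower genes, and the interactions had 1 and 7 genes.

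The list of coagulation and fibrinolysis genes (19 measured) was followed through the heat comparisons because the title of the series names coagulopathy. At Tcmax in saline mice 0 rose and 2 fell, the initiator tissue factor F3 at -0.99 ± 0.28 (adjusted p = 0.0069) and the plasminogen activator Plau at -0.78 ± 0.22 (adjusted p = 0.0083), and the list did not pass (camera adjusted p = 0.70). After poly I:C the same 2 genes fell, F3 at -0.80 ± 0.26 (adjusted p = 0.025) and Plau at -0.77 ± 0.21 (adjusted p = 0.0079). The fall of Plau did not pass in saline without unheated saline Tcmax replicate 2 (adjusted p = 0.06) or after poly I:C with only the groups compared (adjusted p = 0.056). At 1 day in saline mice 9 rose and 2 fell (9 and 3 over the list alone, median 0.47) without a list call (camera adjusted p = 0.14). Fgg, the protease inhibitor Serpine2 at 1.04 ± 0.17 (adjusted p = 0.00016) and the plasminogen-binding Anxa2 at 0.98 ± 0.22 were among the higher genes. The plasmin inhibitor Serpinf2 at -0.82 ± 0.13 (adjusted p = 9.8e-05) and the anticoagulant Proc at -0.46 ± 0.11 were the lower ones. At 1 day after poly I:C 7 rose and 3 fell (10 and 4 over the list alone), with S100a10, the partner of Anxa2, at 1.37 ± 0.28 (adjusted p = 0.00072) and Serpinf2 at -0.91 ± 0.15 (adjusted p = 0.00011). The list passed camera at adjusted p = 0.044 but not with an estimated correlation (adjusted p = 0.41). F3 turned direction with time, differing by 1.86 ± 0.37 (adjusted p = 0.00062) in saline and 1.50 ± 0.39 (adjusted p = 0.0075) in poly I:C mice. Its rise at 1 day in saline (0.87 ± 0.25, adjusted p = 0.018) ended with quantile normalization (adjusted p = 0.062), equal medians (adjusted p = 0.081), no filter (adjusted p = 0.054) or without heated saline 1 day replicate 4 (0.64, adjusted p = 0.09). After poly I:C its rise at 1 day did not pass (0.70 ± 0.29, adjusted p = 0.076). Its fall at Tcmax after poly I:C ended with those 3 settings (adjusted p = 0.10, 0.091 and 0.068) and with an offset of 10 (adjusted p = 0.078). It also ended without heated poly I:C replicate 1 (adjusted p = 0.08) or unheated poly I:C replicates 1 (adjusted p = 0.056), 4 (adjusted p = 0.052) or 7 (adjusted p = 0.057). Among genes too low for the main filter, Fgb, the fibrinogen beta chain, rose when 18047 genes at 1 TPM in 4 libraries were tested, at 1 day in saline (1.58, adjusted p = 0.045) and after poly I:C (1.99, adjusted p = 0.018). The endothelial Vwf did not pass.

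**Figure D4:**
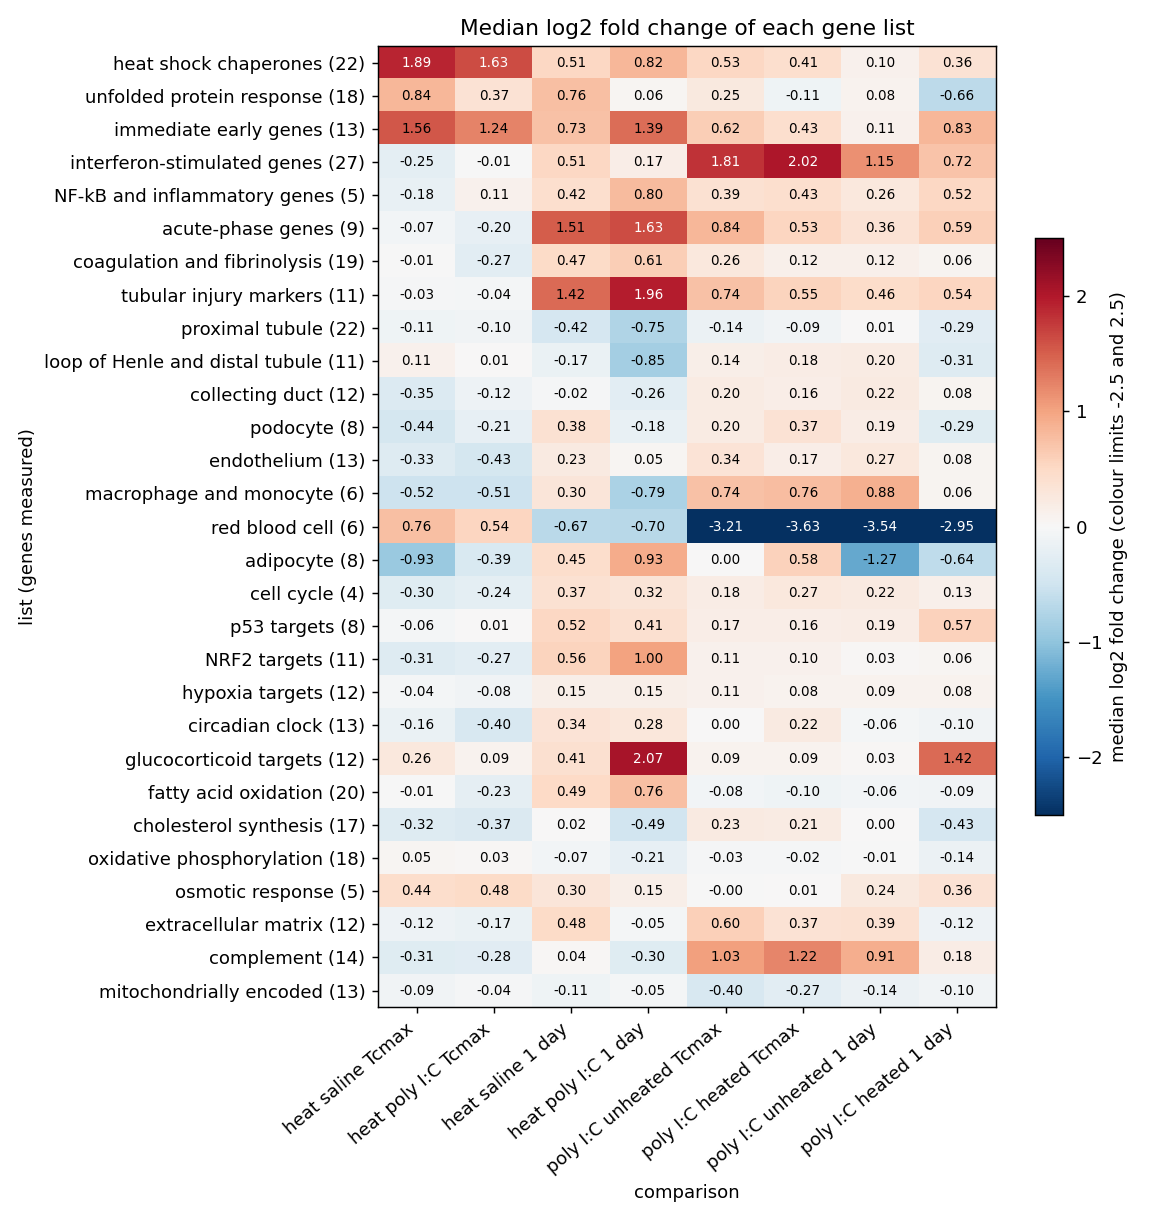
Each cell gives the median log2 fold change of the measured genes of 1 of 29 lists (vertical axis, number measured in brackets) in 1 of 8 comparisons (horizontal axis), with colour limits at -2.5 and 2.5. Heat shock chaperones had medians of 1.89 and 1.63 for heat at Tcmax, and red blood cell genes had -3.21, -3.63, -3.54 and -2.95 for poly I:C.

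Of 377 list tests over 13 comparisons, 127 passed camera and 18 also passed with an estimated correlation. These 18 included heat shock chaperones for heat at Tcmax in both injections and interferon-stimulated and red blood cell genes for poly I:C in all 4 settings. They also included complement for poly I:C in 3 settings, the mitochondrially encoded genes in the same 3, macrophage and monocyte genes for poly I:C in unheated 1 day mice, and the circadian clock between time points. The complement and the macrophage lists both hold C1qa, C1qb and C1qc, so their calls are not separate findings. Other lists share genes too. Cdkn1a is in the tubular injury, p53 and glucocorticoid lists, and Per1 in the glucocorticoid and clock lists. Pdk4 and Angptl4 are in the glucocorticoid and fatty acid oxidation lists, and Fga and Fgg in the acute-phase and coagulation lists. The calls of these lists are not fully separate either. Of the lists without a call in a heat comparison, hypoxia targets had 2 genes higher and 3 lower of 12 at Tcmax in saline (camera adjusted p = 0.70) and 1 higher and 1 lower at 1 day (adjusted p = 0.71). Endothelial genes had 0 higher and 6 lower of 13 for heat at Tcmax after poly I:C, with a median of -0.43 (adjusted p = 0.052). Cell cycle genes had 1 higher of 4 at 1 day in saline (adjusted p = 0.145), and extracellular matrix genes 1 higher of 12 (3 over the list alone, adjusted p = 0.16). Adipocyte genes had 0 higher and 0 lower of 8 for poly I:C in unheated 1 day mice although the list passed as lower (median -1.27, adjusted p = 2.1e-08, adjusted p = 0.11 with an estimated correlation). Of 12 collecting duct genes 0 rose and 3 fell for heat at 1 day after poly I:C (adjusted p = 0.034, adjusted p = 0.40 with an estimated correlation). The neutrophil, lymphocyte and adrenal lists had 0 genes past the low-value filter.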

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

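Of the tests in this part, the 13 comparisons with other groupings of the libraries and the test of a few rising genes were set beforehand, and the other tests were chosen after the result was seen.

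A library far from the rest of its group was looked for in 11 measures over the groups, by the gap to the nearest library divided by the range of the group. It was found in 9 of 88 group values, and chance alone marks about 1 in 20 groups. Hspa1a in the library labelled unheated poly I:C Tcmax replicate 6 had a ratio of 0.916 (2133.5 TPM, nearest 10.4 TPM). Adrenal markers in heated saline 1 day replicate 4 had a ratio of 0.921, with a sum of 1046.6 TPM. The same library had the lowest Egf of its group (44.5 TPM, ratio 0.714). Irf7 was highest in unheated poly I:C 1 day replicate 2 (178 TPM, ratio 0.893) and in unheated poly I:C Tcmax replicate 4 (640.05 TPM, ratio 0.670). Ddit3 was highest in heated poly I:C 1 day replicate 5 (93.9 TPM, ratio 0.857), and Lcn2 was lowest in replicate 6 of that group (5.34 TPM, next 359 TPM, ratio 0.774). Hba-a1 was highest in heated poly I:C Tcmax replicate 1 (32.6 TPM, ratio 0.734). The number of genes at 1 TPM or more set heated saline Tcmax replicate 4 apart (14070 genes, ratio 0.726).

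A tested difference between 2 effects also called for a closer look. The heat effect differed between injections at Tcmax for Ddit3 (-1.96). At 1 day it differed for Sdf2l1 (-1.82), Col15a1 (-1.78), Pdia6 (-1.01), Ostc (-0.94), Stoml2 (-0.88), Ogfod3 (-0.84) and Mrpl3 (-0.84). Between 1 day and Tcmax, the heat effect in saline mice differed for Hspa1a (-6.38), Lcn2 (4.05), Havcr1 (5.38) and Fgg (2.71). In poly I:C mice it differed for Hspa1a (-4.09), Lcn2 (5.26), Havcr1 (4.27) and Fgg (3.68). Fgg in saline mice no longer passed without heated saline 1 day replicate 4 (2.11, adjusted p = 0.058) or with equal medians (adjusted p = 0.075), with adjusted p from 0.0025 to 0.078 over all alternatives. The differences of Hspa1a in poly I:C mice and of Lcn2 and Fgg without single libraries are given in the report.

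The library labelled unheated poly I:C Tcmax replicate 6 stood with the heated libraries. Over the 372 genes that changed at least 2-fold with heat in saline mice, 94.1% of its values were nearer the heated poly I:C mean, against 3.76% to 6.45% in the other 5 unheated and 90.9% to 94.4% in the heated libraries. A mixture with a large share of unheated RNA is argued against by its median position of 1.09 over the 152 higher genes, where 0 is the unheated and 1 the heated mean and the lowest heated library lay at 0.777. A swap within the 2 groups is argued against because the least typical heated library still had 90.9% of values nearer its own group. A wrong heat label, or a swap with a sample outside these groups, may therefore explain the library, and the labels give 7 unheated and 5 heated mice where the design text names 6 and 6. Unplanned heating of this mouse was not tested.

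Globin transcripts were lower with poly I:C in all 4 comparisons. Summed globin TPM was 113 ± 46.0 against 1139 ± 482 in unheated Tcmax libraries (n = 6 and 4), and 174 against 2428, 109 against 1317 and 87.7 against 739 in the others. The TPM scale is argued against because the median change after rescaling stayed at -3.42 or lower, and reads shared between globin copies because the summed TPM changed by -3.08 or more in size. Less blood in the kidney stays open. Platelet transcripts changed by at most -0.56 in the direction needed but were near the floor. The genes of the platelet list summed to 8.32 to 12.7 TPM, and only 1 of them was past the low-value filter. A fall of globin transcripts in blood after poly I:C may be a biological explanation and was not tested.

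Most genes that passed for heat at Tcmax in saline mice were lower. Mitochondrial and non-coding transcripts taking more of the total are argued against, because 73.8% of calls were still lower after TPM was rescaled over nuclear protein-coding genes. A few rising genes taking more of the total cannot be told apart from a wide fall, since genes that rose gained 6.14% of TPM and genes that fell changed by -5.18%, and the median of all genes was -0.18. The split itself depended on this, as equal medians gave 1145 higher and 1170 lower genes. A lower total of messenger RNA per kidney may also give such a split and could not be tested from TPM.

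Other groupings of the same libraries, 100 in each comparison with the real one included, were compared by the number of genes passing. Only the real grouping, 1 of 100, had as many genes for heat in saline mice at Tcmax (real 2581, highest other 383) and 1 day (real 1317, highest other 1130). The same held for poly I:C in unheated Tcmax (real 478, other 235), heated Tcmax (real 321, other 188) and unheated 1 day mice (real 97, other 22). It also held for the difference over time in saline (real 2820, other 7) and in poly I:C mice (real 1758, other 1334). Chance is argued against for these counts. The grouping with 1130 genes exchanged heated saline replicate 6 with unheated saline replicate 4. For heat at Tcmax after poly I:C, 2 of 100 had as many (real 1982, highest other 2147). The higher count exchanged heated replicate 5 with the library labelled unheated replicate 6. For heat at 1 day after poly I:C, 3 of 100 had as many (real 2106, highest other 3245). For poly I:C in heated 1 day mice, 4 of 100 had as many (real 1280, highest other 2436). The test does not exclude chance for heat after poly I:C at either time point or for poly I:C in heated 1 day mice. In each, another grouping gave more genes than the real one. With only the groups compared, 8 and 41 genes passed for heat after poly I:C and for poly I:C in heated mice at 1 day. The shares of 100 groupings were not adjusted over the comparisons. The grouping with 3245 genes set heated replicates 1, 3, 4 and 5 against the unheated libraries together with heated replicate 6. The grouping with 2436 genes exchanged heated saline replicates 3 and 4 with heated poly I:C replicates 5 and 6. Chance was not excluded for the interaction at 1 day (5, real 7, other 561), and a grouping with 561 genes points to a structure of the samples, which was not identified here. For time in unheated saline mice the real count was 0, so all 100 groupings had as many (highest other 4) and nothing about chance follows. For the interaction at Tcmax 1 of 100 had as many (real 1, other 0), which does not exclude chance, as the count rests on Ddit3 alone and was 0 without any 1 of 10 libraries.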

How the results depend on the processing

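The first 9 kinds of alternative were set beforehand, and the filter at 1 TPM in 4 libraries, the removal of the library labelled unheated poly I:C Tcmax replicate 6, the rescaling over nuclear protein-coding genes and the covariate of detected genes were chosen after the data were seen. No paired analysis was possible because the labels carry no number that links single mice of different groups. The title prefixes, which several mice of different groups share, entered as a covariate. They were spread unevenly over the groups. At 1 day most heated poly I:C libraries carried 16, while most heated saline and most unheated poly I:C libraries carried 14 or 15. Poly I:C in heated 1 day mice, heat at 1 day after poly I:C, and the differences built on them were therefore partly confounded with the prefix. For heat at 1 day after poly I:C, the title number as covariate ended the camera calls of the coagulation, circadian and collecting duct lists (adjusted p = 0.055, 0.055 and 0.065). Numbers below are genes passing, beside the main count named in the report, and where no construction shows the reason the cause was not tested. With a mean of at least 50 TPM fewer genes were tested, and 745 and 536 passed for heat at Tcmax (saline, poly I:C), 749 and 1085 for heat at 1 day, 268, 129, 36 and 620 for poly I:C (unheated Tcmax, heated Tcmax, unheated 1 day, heated 1 day), 33 for the interaction at 1 day, and 819 and 631 for heat by time (saline, poly I:C). With no filter on low values 784 passed for heat at 1 day in saline, 0 for the interaction at Tcmax and 3 for time. Quantile normalization gave 859 for heat at 1 day in saline, 205 for poly I:C in heated Tcmax mice, 2 and 29 for the interactions (Tcmax, 1 day) and 1160 for heat by time in saline. Equal medians gave 829 for heat at 1 day in saline, 286 for poly I:C in unheated Tcmax mice, 2 and 11 for the interactions, and 1427 for heat by time in saline. Only the groups compared gave 8 for heat at 1 day after poly I:C, 616 and 41 for poly I:C in heated mice (Tcmax, 1 day), 0 and 0 for the interactions, 970 for heat by time in poly I:C mice and 2 for time. Sample weights gave 4118 for heat at Tcmax after poly I:C, 2012 for heat at 1 day in saline, 1321, 802, 441 and 2080 for poly I:C in the order above, 3 and 1038 for the interactions, 3659 for heat by time in poly I:C mice and 13 for time. The interaction at Tcmax was 0 with an offset of 10, with the title number as covariate and with the filter at 1 TPM in 4 libraries, which gave 1 for time. Rescaling over nuclear protein-coding genes gave 286 and detected genes as covariate 310 for poly I:C in unheated Tcmax mice. Without unheated poly I:C Tcmax replicate 6 in every comparison, 48 passed for the interaction at 1 day, 372 and 107 for poly I:C in heated Tcmax and unheated 1 day mice.

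Leaving out 1 library at a time gave 1824 to 2489 genes for heat at Tcmax in saline, 1433 to 2900 after poly I:C, 551 to 1589 for heat at 1 day in saline and 1138 to 3021 after poly I:C. For poly I:C the ranges were 319 to 486 (unheated Tcmax), 207 to 308 (heated Tcmax), 53 to 94 (unheated 1 day) and 419 to 2535 (heated 1 day). The interactions gave 0 to 2 at Tcmax and 0 to 831 at 1 day, heat by time 2060 to 3037 in saline and 1176 to 2512 in poly I:C mice, and time 0 to 3. The libraries behind changes of more than 1.5 times are named with their counts in the report.

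The direction of 4 list results turned. The mitochondrially encoded list for heat at 1 day in saline turned with quantile normalization (adjusted p = 0.465). The heat shock list for poly I:C in unheated Tcmax mice turned without the library labelled replicate 6 (0.681). The proximal tubule list for poly I:C in unheated 1 day mice turned with fry (0.962), and the interferon list for the interaction at Tcmax turned with a mean of at least 50 TPM (0.985).

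Of 10885 values for named genes under the alternatives, some of them for genes that did not pass in the main test, 10152 had the outcome of the main test, 714 lost a call, 19 gained one and 0 turned direction. Of the 437 genes and comparisons that passed, 138 lost the call with only the groups compared. Leaving out 1 library at a time lost it in 363 of 5697 values. Of 1634 list values, 1335 led to the same call and 295 lost it, 109 of them with an estimated correlation, 50 with fry and 35 with a mean of at least 50 TPM.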

Other observations

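The relations of Fgg and the choice of Cyp24a1 were made after the values were seen. The filter at 1 TPM in 4 libraries, on which the calls of Ccl2, Cxcl1 and Il6 rest, was also chosen after the data were seen. The other values of this part come from the comparisons set beforehand.

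Cyp24a1, the enzyme that breaks down active vitamin D, fell with heat at Tcmax by log2 -4.44 ± 0.74 in saline (limma adjusted p = 3.2e-05, n = 6 and 4) and by -3.76 ± 0.69 in poly I:C mice (adjusted p = 0.00017, n = 5 and 6). Its level was 64.2 ± 29.5 TPM in unheated and 2.25 ± 2.07 TPM in heated saline libraries, and 93.0 ± 54.9 TPM and 3.69 ± 2.32 TPM in the poly I:C libraries. The library labelled unheated poly I:C Tcmax replicate 6 had 1.79 TPM, and without it the Cyp24a1 change in poly I:C mice was -4.64. It passed in every alternative run for these comparisons, with adjusted p up to 0.00044 and 0.017. At 1 day its level was 27.6 ± 24.4 TPM in heated and 34.6 ± 26.6 TPM in unheated saline libraries.

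Among genes too low for the main filter, the chemokine Ccl2 rose with poly I:C in unheated Tcmax mice (2.00, adjusted p = 0.00081) and in heated mice at Tcmax (1.66, adjusted p = 0.0039) and 1 day (1.26, adjusted p = 0.026) when 18047 genes were tested. With the same filter the neutrophil chemokine Cxcl1 (2.30, adjusted p = 0.0074) and the cytokine Il6 (1.63, adjusted p = 0.022) rose with heat at 1 day after poly I:C. Il6 stood at 7.04 ± 12.3 TPM in that group (n = 5), with 28.7 TPM in replicate 5, which also had the highest Hspa1a of the group at 924 TPM. In replicate 6 of that group Lcn2 was 5.34 TPM and Fgg 10.0 TPM, near the unheated levels, while Havcr1 was 29.7 TPM.

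The first hypothesis is that fibrinogen expression in the kidney 1 day after heat follows the degree of tubular injury of each mouse. Over 11 heated 1 day libraries centred on their injection group, log2 Fgg went with log2 Lcn2 at r = 0.949 (permutation p = 0.00019, adjusted over 4 relations 0.00038) and rho = 0.927 (permutation p = 0.00017, adjusted 0.00068), and at r = 0.942 without the 2 farthest libraries. For Havcr1 r was 0.816 and rho 0.855, for Krt20 0.953 and 0.909, and for Egf -0.810 and -0.836. Lcn2 is in the acute-phase list together with Fgg, while Havcr1, Krt20 and Egf are not. The relation with Lcn2 alone does not tell tubular injury from an acute-phase response. The heated 1 day libraries also differed widely as a whole, from -10.2 to 58.7 on the second principal component. How many other genes went with Fgg as closely was not counted. The permutation p therefore tests independence of 2 genes only, and does not set tubular injury apart from the size of the whole heat response. In the 6 saline libraries alone r with Lcn2 was 0.975 (exact permutation p = 0.0069) and rho 0.943 (exact permutation p = 0.017). These include heated saline 1 day replicate 4, which carried adrenal markers. Over the 10 libraries without it, Fgg went with Lcn2 at r = 0.934 (permutation p = 0.0011, adjusted 0.0022) and rho = 0.855 (permutation p = 0.0029, adjusted 0.0058), while rho with Egf was -0.673 (permutation p = 0.074). The 5 saline libraries left were not tested alone. The relation was not tested in the 5 poly I:C libraries alone, nor within the title prefixes. A shared source such as the same injured tubule cells may explain the relation, and staining for fibrinogen and KIM-1 in sections of the same kidneys, with plasma creatinine, would test it.

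The second hypothesis is that poly I:C blunts the endoplasmic reticulum response that follows heat. At 1 day the difference was -1.82 for Sdf2l1 and -1.01 for Pdia6. The unfolded protein response list had 0 risen and 2 fallen genes (11 over the list alone). Its camera call was lost with an estimated correlation (adjusted p = 0.59). Ddit3 of the same list was not lower with poly I:C. It stood at 68.9 ± 14.1 TPM in heated and 28.8 ± 2.94 TPM in unheated poly I:C libraries (n = 5 and 4). In saline libraries it stood at 20.4 ± 10.6 TPM in heated and 10.9 ± 2.84 TPM in unheated mice (n = 6 and 6). The number of genes passing could reflect the structure of the heated libraries, since it was 0 with only the groups compared and 1038 with sample weights, and 5 of 100 groupings gave as many as the real 7. Western blots of HSPA5 and PDIA6 in kidneys of all 4 groups at 1 day would test it.

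The third hypothesis is that mice given poly I:C had a stronger glucocorticoid signal 1 day after heat. Of 12 targets 10 rose for poly I:C in heated mice, with Fkbp5 at 1.28 ± 0.29 (adjusted p = 0.0035), yet the interaction had 0 genes passing in limma and Fkbp5 at 1.37 ± 0.42 (adjusted p = 0.12). With only the groups compared Fkbp5 did not pass for poly I:C in heated mice (adjusted p = 0.22). Its interaction passed with sample weights (adjusted p = 0.0025) and without heated poly I:C 1 day replicate 4 (0.02) or 6 (0.0077), and did not pass in the other alternatives, with adjusted p up to 0.37. With an estimated correlation the list did not pass for poly I:C in heated mice (adjusted p = 0.14) or in the interaction (0.17). The list shares Cdkn1a with the tubular injury markers, Pdk4 and Angptl4 with fatty acid oxidation, and Per1 with the circadian clock. Plasma corticosterone at 1 day in the same 4 groups would test it.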
